A study of Homo sapiens with 6 samples.

How the data were processed

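RNA-seq libraries were made from total RNA of untreated RPMI-8226, RPMI-8226-R and NCI-BL2171 cells after removal of ribosomal RNA, per the labels, with 2 libraries per line. The authors deposited 1 table per library with the length, effective length, TPM and number of reads of each gene. The deposited estimated counts of reads need not be whole and were rounded to whole numbers before testing. The deposited TPM values were made by the authors from the same estimates, per the file headers and the values. Lengths and effective lengths are another deposited unit, given in bases, and were used only for an offset and for length trends. The genome build is GRCh38.p13 per the submitters' processing notes. The quantifier, its version, its annotation and whether it used strand are not given in the sources used here; reads of near-identical copies and of overlapping or antisense genes can therefore be split in ways that were not checked.

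Each table held 61544 genes, of which 46 were copies of genes on the pseudoautosomal part of the Y chromosome (88666 reads in all); these were added to their X copies, leaving 61498 genes. A symbol was matched for 61399 of them, and positions of 58298 were taken from GENCODE 29 (GRCh38); the other 3200 carried at most 0.400% of the reads of a library. Totals per library were 26790603 and 23952370 estimated reads for NCI-BL2171, 29052199 and 27947579 for RPMI-8226 and 25695927 and 26860081 for RPMI-8226-R. A gene without a count in a library can therefore still be expressed at a level below 3 counts in such a total. Chi-square values per gene between the 2 libraries of a line were 5.81, 3.59 and 11.8 for NCI-BL2171, RPMI-8226 and RPMI-8226-R, so no library was a copy of another.

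Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr by line (minimum count 10, minimum total 15), and a robust quasi-likelihood F test over all 6 libraries with 3 residual degrees of freedom, two-sided, adjusted over 20081 genes by the Benjamini-Hochberg method at 0.05. The typical coefficient of biological variation was 6.81%. Levels are TMM-normalised CPM. A gene with no count in a line is compared with a floor of 3 counts per library and written as at least that fold; with 1 to 3 counts in a line the ratio of counts is given with a 95% interval. Such intervals and floors cover counting error only. Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 35 lists, and again with an estimated correlation. The lists hold 902 genes, 901 of which were matched to a gene. All 35 are reported for RPMI-8226-R against RPMI-8226; for the other comparisons those with most bearing on the lines are given.

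The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes PSMB5 everywhere; the 10 largest rises and falls in RPMI-8226-R against RPMI-8226 and the 5 largest each way in the other comparisons, among protein-coding genes past the threshold with a mean of at least 5 TPM in the higher line and no overlap between lines; up to 2 rises and 2 falls of each list; and, of the PI3K-AKT-mTOR lists, every member past the threshold with at least a 2-fold change, with preset genes, among them MTOR, DEPTOR, AKT1, AKT2, PIK3CA and PIK3CD, whatever their change, and any member of the 20S and ABC transporter lists. Genes of the Y chromosome and variable segments of antigen receptors were never named, and some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

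The procedure was tested on simulated data with 200 genes changed. For RPMI-8226-R against RPMI-8226, over 18115 genes, 77.6% of the 1.5-fold, 88.1% of the 2-fold and 93.9% of the 4-fold changes were recovered, and 16 of 189 calls were of unchanged genes. For RPMI-8226 against NCI-BL2171, over 17020 genes, the shares were 65.7%, 88.1% and 100%, with 13 of 182 calls of unchanged genes. For RPMI-8226-R against NCI-BL2171, over 17033 genes, they were 65.7%, 80.6% and 92.4%, with 14 of 173. In each comparison the share of calls that were of unchanged genes lay above 0.05. As many genes were raised as lowered, and all others were the same in every line. In the data most tested genes were called in each comparison. The simulation therefore cannot show errors of scaling between lines that differ so widely. For RPMI-8226-R against RPMI-8226 the list test recovered the 1 shifted list and called 0 others. The simulated genes varied independently and all genes outside that list were unchanged. In the data the estimated correlation was 0.765 for the 20S core and 0.696 for ribosomal proteins. The simulation therefore cannot show how often the list test calls correlated lists falsely. The alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom, limma-trend on log2(TPM + 1), an effective-length offset, protein-coding genes alone, no filter or at least 50 counts in 2 libraries, the 4 libraries of the lines compared, the replicate number as a block, a 2-fold minimum, leaving out each library, and for lists fry and an estimated correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.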

Results

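Expression was measured by RNA-seq of ribosomal RNA-depleted total RNA in 3 human cell lines, with 2 libraries per line and no treatment in any of them. RPMI-8226 is a line from a patient with multiple myeloma, a cancer of antibody-secreting plasma cells. RPMI-8226-R is its derivative resistant to bortezomib, a drug that blocks the chymotrypsin-like site of the proteasome. NCI-BL2171 is labelled as a line of B lymphocytes. The 6 libraries held between 23952370 and 29052199 estimated reads each. Log2(TPM + 1) values of the 2 libraries of a line correlated across genes at 0.996 for NCI-BL2171, 0.995 for RPMI-8226 and 0.995 for RPMI-8226-R (Pearson; genes are not independent replicates), against values from 0.893 to 0.962 between lines. Levels are given as TMM-normalised CPM, mean ± SD over 2 libraries per line, and log2 fold changes as estimate ± SE. The labels do not say that the libraries of a line came from separate cultures, so that p-values measure only the spread between these libraries, which may be technical.

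The lines differed in the markers of their cell types. JCHAIN, the joining chain of secreted antibodies, stood at 1439 ± 79.2 TPM in RPMI-8226 and 3177 ± 42.9 TPM in RPMI-8226-R, and the lambda light chain constant gene IGLC2 at 53350 ± 1753 and 29570 ± 663 TPM. The libraries labelled NCI-BL2171 held 0 TPM of JCHAIN and 0.123 ± 0.174 TPM of IGLC2. They carried instead the alpha globin gene HBA1 at 3569 ± 102 TPM and the erythroid haem enzyme ALAS2 at 67.96 ± 6.60 TPM, which are products of the red cell lineage. CD74, the MHC class II chaperone abundant in B cells and chosen here after its values were seen, was at 0.272 ± 0.0523 TPM in them, 5520 ± 113 TPM in RPMI-8226 and 137 ± 4.36 TPM in RPMI-8226-R. Because these values go against the label, this group is called the libraries labelled NCI-BL2171.

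**Figure D1:**
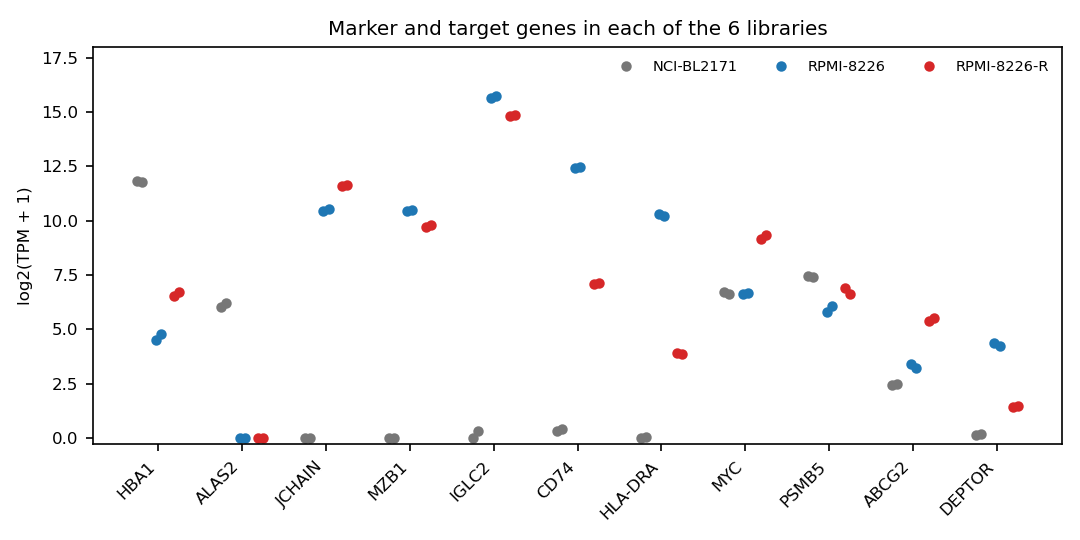
Level of 11 genes in each of the 6 libraries; each point is 1 library. The vertical axis is log2(TPM + 1), and colours mark the 3 lines. The libraries labelled NCI-BL2171 carry HBA1 and ALAS2 and lack JCHAIN and MZB1, while CD74 and HLA-DRA (both chosen after their values were seen) and DEPTOR are lower and MYC, PSMB5 and ABCG2 higher in RPMI-8226-R than in RPMI-8226.

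The comparison of RPMI-8226-R with RPMI-8226 asks how the bortezomib-resistant derivative differs from its parent, with the PI3K-mTOR pathway named by the study as a focus. MYC, the growth-promoting transcription factor, was 4.82-fold higher in RPMI-8226-R, at 1015 ± 26.5 against 210.5 ± 3.07 CPM. The drug efflux transporter ABCG2 was 3.77-fold higher, at 114 ± 1.63 against 30.2 ± 0.00848 CPM. Of the sterol and fatty acid synthesis genes 24 of 28 rose, whereas 13 of 13 MHC class II genes, 23 of 27 NF-kB genes, 27 of 33 interferon-stimulated genes, 31 of 35 glycolysis and hypoxia genes and 74 of 75 ribosomal protein mRNAs fell. None of these lists passed against other genes with an estimated correlation (camera adjusted p from 0.225 to 0.445). DEPTOR, an inhibitor bound to mTOR, fell from 49.96 ± 1.33 to 3.58 ± 0.283 CPM. PSMB5, the proteasome subunit that bortezomib binds (ENSG00000100804.19; chromosome 14, 23016543 to 23035230, GRCh38), was 1.37-fold higher at 72.8 ± 8.86 against 53.1 ± 1.70 CPM, a log2 fold change of 0.45 ± 0.09 (edgeR adjusted p = 1.4e-04).

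Among protein-coding genes with a mean of at least 5 TPM in the higher line and no overlap between the libraries of the lines, the largest rises were those of CREG2, ROBO2, RAI2, CHST4, DMRT3, KEL, DMRT1, FSTL4, F3 and COX7B2. ROBO2, a receptor of the axon guidance protein SLIT (ENSG00000185008.18; chromosome 3, 75906695 to 77649964), went from 2.06 ± 0.290 to 149.9 ± 4.71 CPM, a log2 fold change of 6.18 ± 0.13 (edgeR adjusted p = 2.3e-19). CREG2 had 3 counts in RPMI-8226 in total, and its count ratio (RPMI-8226-R over RPMI-8226) was 119.7 (95% counting interval 40.6 to 583). The coagulation initiator F3 (tissue factor) rose 21.8-fold and the transcription factors DMRT3 and DMRT1, which lie near each other on chromosome 9, rose 26.4-fold and 24.3-fold. The largest falls were those of OLFML2A, EDIL3, HLA-DQB2, HLA-DQA2, CD80, CCL19, CCL22, HLA-DQA1, UBD and HLA-DOA. OLFML2A (ENSG00000185585.20; chromosome 9, 124777158 to 124814885) stood at 96.9 ± 4.85 CPM in RPMI-8226 and had no count in RPMI-8226-R, which made it at least 901-fold lower. By the same measure the integrin ligand EDIL3 was at least 560.1-fold lower, HLA-DQB2 at least 135-fold lower, the T cell costimulator CD80 at least 103-fold lower and the chemokine CCL19 at least 84.7-fold lower. CCL22, a chemokine induced by NF-kB, fell from 241 ± 9.89 to 0.122 ± 0.121 CPM. The ubiquitin-like modifier UBD (RPMI-8226 over RPMI-8226-R) had a count ratio of 1916 (95% counting interval 529.9 to 15820), and HLA-DQA2 one of 3155 (95% counting interval 1079 to 15300). HLA-DQA1 and HLA-DQA2 are near-identical copies that share reads, and their separate values are uncertain.

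Genes of the PI3K-AKT-mTOR pathway moved in both directions. Of 51 measured activators and effectors, 25 rose, 16 fell and 10 did not pass, with the same numbers adjusted over the list alone. Against all other genes the list did not pass (camera adjusted p = 0.116, adjusted p = 0.375 with an estimated correlation), and its median of 0.27 and mean of -0.05 differed in sign. PIK3R3, a regulatory subunit of PI3K, rose 3.35-fold to 141 ± 1.04 CPM. RPTOR, the defining subunit of mTORC1, rose 3.13-fold to 30.2 ± 0.211 CPM, and RPS6KB1, the S6 kinase that mTORC1 activates, rose 2.86-fold to 67.9 ± 0.166 CPM. PDPK1, the kinase that activates AKT, the translation initiation scaffold EIF4G1, the lysosomal amino acid sensor SLC38A9, the adaptor PIK3AP1 and the GTPase RRAGB rose by log2 fold changes of 1.06, 1.16, 1.09, 1.19 and 1.07. SGK1, a kinase related to AKT, fell 64.7-fold, from 38.6 ± 0.0714 to 0.594 ± 0.105 CPM. The catalytic subunit PIK3CD fell 7.49-fold, and the GTPases RRAGD and RHEB, which act on mTORC1, and the adaptor GAB2 fell by log2 fold changes of -2.12, -1.31 and -1.25. Changes of AKT1 (0.36 ± 0.07), AKT2 (0.56 ± 0.07), MTOR (0.45 ± 0.08) and PIK3CA (-0.70 ± 0.08) were smaller on the log2 scale. The calls of RRAGB and MTOR were lost with an offset for effective gene length (0.54 and 0.27), and those of RRAGB, GAB2 and PIK3CA with limma-trend on log2(TPM + 1) (0.72, -0.07 and -0.50).

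Of 29 measured negative regulators of the pathway, 8 rose, 14 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.225, adjusted p = 0.445 with an estimated correlation). DEPTOR fell 13.9-fold (-3.80 ± 0.13; edgeR adjusted p = 5.7e-16) and the PI3K inhibitor PIK3IP1 fell 9.67-fold. SESN2 and SESN1, sensors that restrain mTORC1 in stress and amino acid shortage, fell 6.24-fold and 5.09-fold. DDIT4, an mTORC1 inhibitor induced by hypoxia and stress, fell from 1611 ± 58.6 to 425 ± 20.8 CPM, and its relative DDIT4L, the arginine sensor CASTOR1 and the phosphatases INPP4B and INPP5J fell by log2 fold changes of -2.89, -3.08, -3.48 and -2.65. For genes that respond to stress or hypoxia, a difference in culture state cannot be told apart from one between the lines in this design. The call of INPP5J was lost with limma-trend on log2(TPM + 1) (-0.30). TRIB3, a pseudokinase that binds AKT, and AKT1S1, the mTORC1 substrate PRAS40, rose 3.37-fold and 2.74-fold. GRB10 passed with at most 3 counts in any library of either line and is given no fold. AKT lowers genes that FOXO factors activate by excluding these factors from the nucleus. The list of FOXO-linked genes also holds FOXO genes themselves and shares BNIP3 with the glycolysis and hypoxia list. AKT activity was not measured. Of 20 measured FOXO-linked genes, 1 rose, 16 fell and 3 did not pass, the same adjusted over the list alone (median -1.11, -1.11 with genes at 0 counts in a group at their bound, -0.52 on the TPM scale; camera adjusted p = 2.5e-05, adjusted p = 0.296 with an estimated correlation). The transcriptional repressor BCL6 fell 53.1-fold, and SESN1 and PIK3IP1 belong to this list as well.

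**Figure D2:**
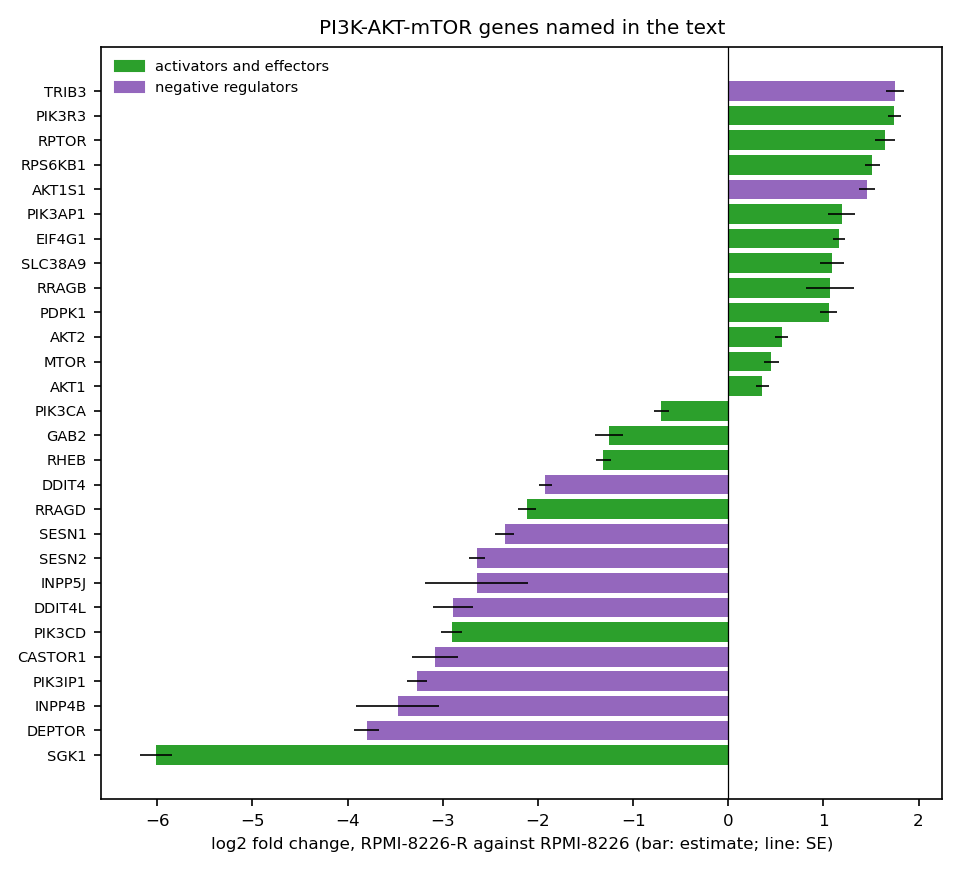
Log2 fold change of RPMI-8226-R against RPMI-8226 for genes of the PI3K-AKT-mTOR lists named in the text, on the horizontal axis; bars start at 0 and give the edgeR estimate, lines give its SE, green marks activators and effectors and purple negative regulators. SGK1 (-6.02) and DEPTOR (-3.80) have the most negative values shown and TRIB3 (1.75) the most positive.

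Of 14 genes of the 20S core, 9 rose, 0 fell and 5 did not pass, the same adjusted over the list alone, led by PSMA3 (1.81-fold) and PSMA5 (1.59-fold) (median 0.26, 0.63 on the TPM scale; camera adjusted p = 0.00983, adjusted p = 0.587 with an estimated correlation). Of 36 genes of the 19S regulator and of proteasome assembly, 25 rose, 5 fell and 6 did not pass, and 27 rose and 5 fell adjusted over the list alone (median 0.47, 0.81 on the TPM scale; camera adjusted p = 2.4e-05, adjusted p = 0.375 with an estimated correlation). The activator subunit PSME3 rose 3.62-fold and the assembly chaperone PSMG1 3.28-fold. NFE2L1, the transcription factor that restores proteasome genes after proteasome inhibition, fell 2.20-fold, and the small subunit SEM1 fell 1.82-fold. Of 17 genes of the immunoproteasome and MHC class I presentation, 3 rose, 11 fell and 3 did not pass, the same adjusted over the list alone (median -0.56, -0.17 on the TPM scale; camera adjusted p = 0.0149, adjusted p = 0.296 with an estimated correlation). HLA-F was 7.58-fold lower and HLA-E 5.69-fold lower.

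Stress pathways moved unevenly. Of 40 endoplasmic reticulum chaperones and unfolded protein response genes, 7 rose, 22 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0278, adjusted p = 0.375 with an estimated correlation), but the median of -0.20 turned to 0.19 on the TPM scale. In this comparison that scale moved all genes by a median of 0.36. The shift enters every list median given on it, also for the proteasome lists above. The BiP exchange factor SIL1 fell 5.73-fold and EDEM1, of the degradation of misfolded glycoproteins, rose 2.35-fold. ATF4 targets and amino acid supply genes, with 11 up, 17 down and 5 not passing of 33 (12 rose and 17 fell adjusted over the list alone), did not pass as a list (camera adjusted p = 0.240). Their median of -0.20 was 0.14 on the TPM scale. Within the list the stress-induced PPP1R15A and DDIT3 fell 57.7-fold and 41.5-fold, and the cystine transporter SLC7A11 rose 3.53-fold. Of 23 cytosolic heat shock genes 10 rose and 9 fell (11 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.922). The median was 0.11 and the mean -0.62. HSPB8 rose 6.70-fold and HSPA1A, which shares reads with its copy HSPA1B, fell 10.99-fold. NRF2 and redox genes, 17 up and 10 down of 29 and the same adjusted over the list alone, did not pass (camera adjusted p = 0.167). NQO1 was 2.81-fold higher and glutathione peroxidase GPX1 4.01-fold lower. Autophagy and lysosome genes passed as lower, with 3 up, 21 down and 7 not passing of 31 (4 rose and 21 fell adjusted over the list alone; median -0.61, -0.29 on the TPM scale; camera adjusted p = 7.5e-04, adjusted p = 0.225 with an estimated correlation). GABARAPL1, of the autophagosome, fell 18.1-fold. Apoptosis genes, 8 up and 18 down of 33 (8 rose and 19 fell adjusted over the list alone), passed as lower (median -0.50, -0.57 with genes at 0 counts in a group at their bound, -0.10 on the TPM scale; camera adjusted p = 0.0257, adjusted p = 0.363 with an estimated correlation). The caspase inhibitor BIRC3 fell 11.97-fold and CASP8 rose 2.01-fold.

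Of 10 measured genes of ABC drug transporters and the vault particle, 3 rose, 5 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.853). ABCG2 (ENSG00000118777.12; chromosome 4, 88090264 to 88231322) had a log2 fold change of 1.92 ± 0.08 (edgeR adjusted p = 2.2e-14) and ABCC4 one of 1.33 ± 0.09, whereas the vault protein MVP fell 3.08-fold, a call lost with limma-trend on log2(TPM + 1) (-0.90). ABCB1, the P-glycoprotein gene, was at 0.273 ± 0.229 CPM in RPMI-8226 and had no count in RPMI-8226-R, at least 2.54-fold lower, a call lost without the second RPMI-8226 library and with limma-trend on log2(TPM + 1).

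All 13 MHC class II genes, which present antigen to helper T cells, fell, the same adjusted over the list alone (median -7.76, -6.32 on the TPM scale; camera adjusted p = 2.3e-11, adjusted p = 0.225 with an estimated correlation). HLA-DQA1 went from 437 ± 10.4 to 0.2499 ± 0.0386 CPM, HLA-DOA from 142 ± 1.58 to 0.124 ± 0.0700 CPM, and CD74, chosen after its values were seen, from 6122 ± 173 to 122 ± 5.47 CPM. Of 27 NF-kB components and targets, 1 rose, 23 fell and 3 did not pass, the same adjusted over the list alone (median -2.14, -1.96 with genes at 0 counts in a group at their bound, -1.54 on the TPM scale; camera adjusted p = 1.2e-08, adjusted p = 0.296 with an estimated correlation). NFKB1 itself rose 1.78-fold, and CCL22 and BIRC3 were among the falls. Interferon-stimulated genes fell in 27 and rose in 2 of 33 cases, the same adjusted over the list alone (median -2.19, -2.20 with genes at 0 counts in a group at their bound, -1.05 on the TPM scale; camera adjusted p = 1.3e-06, adjusted p = 0.225 with an estimated correlation). IFITM1 was 10.6-fold higher and IFI27 had a count ratio (RPMI-8226 over RPMI-8226-R) of 252 (95% counting interval 44.9 to 10010). Of 29 IL6-JAK-STAT and myeloma growth signal genes, 6 rose and 21 fell, the same adjusted over the list alone (median -0.68, -0.67 with genes at 0 counts in a group at their bound, -0.33 on the TPM scale; camera adjusted p = 0.00522, adjusted p = 0.363 with an estimated correlation). The interleukin 6 receptor IL6R rose 2.50-fold, and the kinase JAK3 fell, with a count ratio (RPMI-8226 over RPMI-8226-R) of 136 (95% counting interval 46.01 to 659.9). B cell identity genes fell in 17 and rose in 5 of 26 cases, the same adjusted over the list alone (median -1.05, -1.05 with genes at 0 counts in a group at their bound, -0.50 on the TPM scale; camera adjusted p = 0.0183, adjusted p = 0.296 with an estimated correlation). MS4A1, the CD20 gene, was at least 63.5-fold lower.

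Genes of the plasma cell programme went both ways. Of 24 plasma cell identity genes 10 rose and 12 fell, the same adjusted over the list alone (camera adjusted p = 0.605). The coactivator POU2AF1 was 2.08-fold higher. Immunoglobulin constant regions, 4 up and 7 down of 13 (4 rose and 8 fell adjusted over the list alone), did not pass as a list (camera adjusted p = 0.333). IGHG3 rose 6.54-fold to 6.30 ± 0.330 CPM and IGHE fell from 5.66 ± 0.272 to 0.106 ± 0.0455 CPM. Myeloma drivers, 6 up and 14 down of 27 (7 rose and 14 fell adjusted over the list alone), did not pass (camera adjusted p = 0.504). Their median of -0.19, -0.19 with genes at 0 counts in a group at their bound, turned to 0.13 on the TPM scale. MYC (ENSG00000136997.21; chromosome 8, 127735434 to 127741434) had a log2 fold change of 2.27 ± 0.06 (edgeR adjusted p = 3.0e-17), the lymphoid transcription factor IKZF3 rose 2.53-fold and MYCL fell 5.14-fold. Adhesion and homing genes, 6 up and 17 down of 28 and the same adjusted over the list alone, did not pass (camera adjusted p = 0.0590). NCAM1, the CD56 antigen of myeloma cells, rose 8.21-fold to 147 ± 5.15 CPM and the chemokine receptor CCR2 rose 5.06-fold.

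Of 28 sterol and fatty acid synthesis genes 24 rose, 2 fell and 2 did not pass, the same adjusted over the list alone (median 1.10, 1.27 on the TPM scale; camera adjusted p = 2.6e-10, adjusted p = 0.296 with an estimated correlation). The fatty acid desaturases FADS2 and FADS1 rose 4.46-fold and 4.08-fold, to 845 ± 53.9 and 493 ± 42.9 CPM, while the sterol carrier STARD4 fell 1.89-fold. Of 35 glycolysis and hypoxia genes 2 rose and 31 fell (2 rose and 32 fell adjusted over the list alone; median -1.48, -1.02 on the TPM scale; camera adjusted p = 1.6e-11, adjusted p = 0.225 with an estimated correlation). The hypoxia-induced ANKRD37 was 20.3-fold lower and the lactate transporter SLC16A1 2.04-fold higher. Nuclear genes of oxidative phosphorylation, 9 up, 22 down and 17 not passing of 48 and the same adjusted over the list alone, did not pass (camera adjusted p = 0.225). Their median of -0.10 was 0.25 on the TPM scale. SDHA of complex II fell 2.32-fold while NDUFA6 of complex I rose 1.53-fold. The mitochondrially encoded mRNAs rose in 9 of 13 cases, with 1 lower, the same adjusted over the list alone (median 1.33, 1.71 on the TPM scale; camera adjusted p = 7.5e-04, adjusted p = 0.545 with an estimated correlation). MT-CYB rose from 861 ± 30.1 to 3254 ± 611 CPM and MT-ND6 rose 9.03-fold. The fall of MT-ND5 (-0.37 ± 0.12) was lost in 4 alternatives, among them the fit of the 4 libraries of both lines.

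Growth and library composition genes were also counted. Of 75 cytosolic ribosomal protein mRNAs 74 fell and 0 rose, the same adjusted over the list alone (median -0.77, -0.38 on the TPM scale; camera adjusted p = 1.5e-14, adjusted p = 0.445 with an estimated correlation). RPS27 was 3.72-fold lower. S phase genes, 13 up and 7 down of 24 and the same adjusted over the list alone, did not pass (camera adjusted p = 0.184). The chromatin assembly factor CHAF1A was 2.19-fold higher and cyclin CCNE2 3.31-fold lower. G2 and mitosis genes fell in 16 and rose in 3 of 24 cases, the same adjusted over the list alone (median -0.53, -0.15 on the TPM scale; camera adjusted p = 0.00680, adjusted p = 0.363 with an estimated correlation), among them the mitotic kinase CDK1, 3.04-fold lower, and the kinesin KIF20A, 3.27-fold lower. Of 16 replication-dependent histone genes 10 fell and 0 rose, the same adjusted over the list alone (median -1.66, -2.01 with genes at 0 counts in a group at their bound, -0.78 on the TPM scale; camera adjusted p = 0.0159, adjusted p = 0.587 with an estimated correlation). H1-2 was 11.7-fold lower. Of 9 abundant non-coding RNAs 3 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.249), SNHG1 by 2.81-fold.

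Markers of other cell types did not pass as lists. T and NK cell markers rose in 1 and fell in 3 of 8 cases (camera adjusted p = 0.955; median -0.07, -0.25 with genes at 0 counts in a group at their bound, mean 1.08), with CD2 at a count ratio (RPMI-8226-R over RPMI-8226) of 189.8 (95% counting interval 33.7 to 7533). Myeloid markers fell in 5 of 7 cases with none higher (camera adjusted p = 0.198), and CD33 fell 4.44-fold. Erythroid markers rose in 2 and fell in 2 of 7 cases (camera adjusted p = 0.468, in the direction of a rise, though the median was 0 and the mean -1.30), where HBA1 and HBA2, which share reads, rose to 46.4 ± 2.37 and 32.7 ± 0.339 CPM from 15.3 ± 2.15 and 15.7 ± 0.571 CPM. Stromal and epithelial markers rose in 2 and fell in 3 of 8 cases (camera adjusted p = 0.857). EPCAM was 2.17-fold higher. For each of these 4 lists the numbers were the same adjusted over the list alone.

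**Figure D3:**
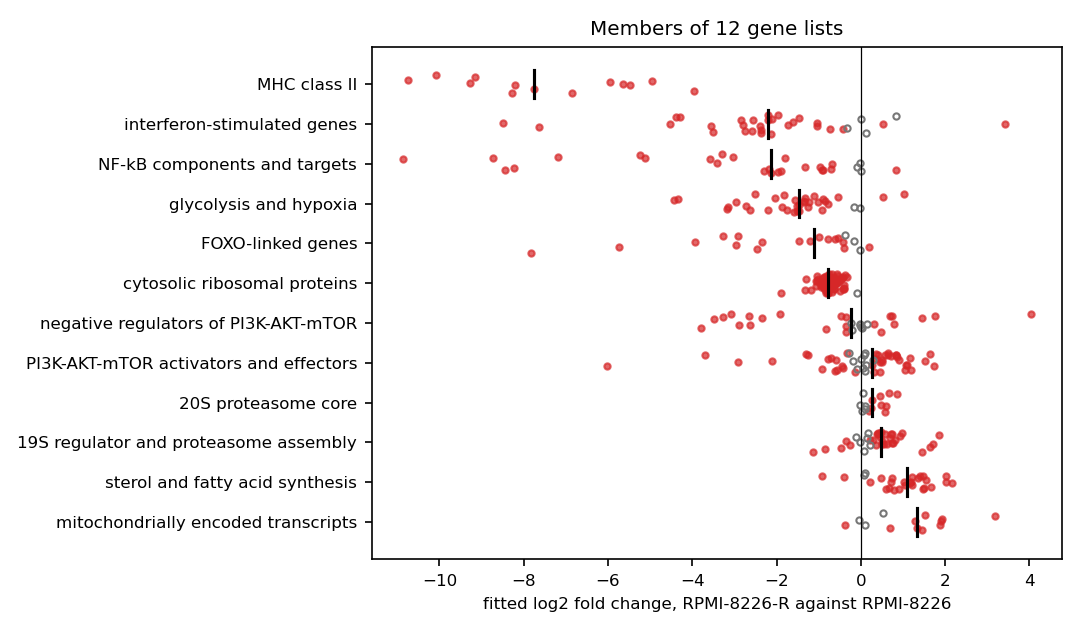
Fitted log2 fold change of RPMI-8226-R against RPMI-8226 (horizontal axis) for the measured members of 12 gene lists. Each point is 1 gene, filled red where the edgeR adjusted p is under 0.05 and open grey otherwise, and the black bar is the list's median. The medians run from -7.76 for MHC class II to 1.33 for mitochondrially encoded transcripts; the most negative points include genes with no count in RPMI-8226-R, whose fitted values are not measured sizes.

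In total 13177 of 20081 genes differed between RPMI-8226-R and RPMI-8226 (edgeR quasi-likelihood test, adjusted p under 0.05), 5716 higher and 7461 lower (43.4% higher), and 6683 of these differed at least 2-fold. Fitted without the libraries labelled NCI-BL2171, the comparison called 12876 genes, 6254 higher and 6622 lower. The balance of directions depends on the scale: limma-trend on log2(TPM + 1), on which the median of all genes lay 0.36 higher, called 7030 genes higher and 4557 lower (60.7% higher). Of 35 lists 18 passed with the preset correlation and 0 with an estimated one. The list calls assume that preset. The loss of all calls is not due to correlation alone, since the estimated test also rests on 3 residual degrees of freedom. The immunoproteasome and MHC class I list had an estimated correlation of -0.00546, below the preset 0.01. Its unadjusted camera p still went from 0.00596 to 0.0595. The 0 calls therefore cannot tell how far the list calls depend on the preset.

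RPMI-8226 was compared with the libraries labelled NCI-BL2171 to set the myeloma line against a line labelled as B lymphocytes. All 24 plasma cell identity genes and 24 of 27 NF-kB genes were higher in RPMI-8226, and 5 of 7 erythroid markers and 23 of 28 sterol and fatty acid synthesis genes were lower. None of these lists passed against other genes with an estimated correlation (camera adjusted p from 0.225 to 0.364). MZB1, a chaperone of antibody secretion, JCHAIN, MAF, a transcription factor activated in myeloma, the chemokine CXCL10 and HLA-DRB1 had the 5 largest rises among protein-coding genes. They had no count in the libraries labelled NCI-BL2171, and were at least 12330-fold, 9911-fold, 7136-fold, 11340-fold and 6369-fold higher. HLA-DRB1 shares reads with HLA-DRB5, as do the lambda constant genes, IgG constant genes and gamma globins among themselves, and their separate values are uncertain. The largest falls included the embryonic globin HBZ, HEMGN and FAF1, at least 9549-fold, 2105-fold and 1431-fold lower. ENSG00000284931, which has no symbol in the tables used, was at least 2716-fold lower. PSMB5 was 2.54-fold lower in RPMI-8226, at 53.1 ± 1.70 against 135 ± 13 CPM (edgeR adjusted p = 2.8e-11).

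Among the lists, all 24 plasma cell identity genes rose (median 5.79, 4.33 with genes at 0 counts in a group at their bound, 3.19 on the TPM scale; camera adjusted p = 2.6e-10, adjusted p = 0.225 with an estimated correlation). So did all 13 MHC class II genes (median 14.26, 10.49 with genes at 0 counts in a group at their bound, 6.94 on the TPM scale; camera adjusted p = 1.5e-09, adjusted p = 0.160 with an estimated correlation), all 13 immunoglobulin constant regions (camera adjusted p = 8.8e-07, adjusted p = 0.142 with an estimated correlation) and all 17 genes of the immunoproteasome and MHC class I (camera adjusted p = 9.9e-10, adjusted p = 0.142 with an estimated correlation). These 4 counts were the same adjusted over the list alone. NF-kB genes rose in 24 and fell in 2 of 27 cases, the same adjusted over the list alone (camera adjusted p = 1.6e-09, adjusted p = 0.302 with an estimated correlation). Interferon-stimulated genes rose in 28 and fell in 4 of 33 cases (28 rose and 5 fell adjusted over the list alone; camera adjusted p = 3.7e-05, adjusted p = 0.225 with an estimated correlation). The antiviral enzymes OAS1 and OAS2 were at least 569-fold and 431-fold higher and IFITM1 was 596-fold lower. Adhesion and homing genes rose in 23 and fell in 5 of 28 cases, the same adjusted over the list alone (camera adjusted p = 8.0e-06, adjusted p = 0.142 with an estimated correlation). The chemokine receptor CCR1 was at least 529-fold higher and the integrin ITGA5 5.09-fold lower. B cell identity genes rose in 16 and fell in 8 of 26 cases, the same adjusted over the list alone (camera adjusted p = 0.0526). IRF8 and FCER2 were at least 534-fold and 368-fold higher, and CD24 at least 295-fold lower. The survival gene BCL2 was at 168 ± 4.58 against 0.171 ± 0.0702 CPM.

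Genes lower in RPMI-8226 than in the libraries labelled NCI-BL2171 included 5 of 7 erythroid markers (camera adjusted p = 0.00464, adjusted p = 0.364 with an estimated correlation), with ALAS2 at least 1011-fold lower while the erythropoietin receptor EPOR was 3.48-fold higher. Sterol and fatty acid synthesis genes fell in 23 and rose in 3 of 28 cases (camera adjusted p = 9.2e-06, adjusted p = 0.364 with an estimated correlation), with HMGCS1, an early enzyme of the mevalonate pathway, 10.5-fold lower. The 20S core, 1 up and 11 down of 14 (camera adjusted p = 0.00464, adjusted p = 0.604 with an estimated correlation), and the 19S regulator and assembly genes, 5 up and 28 down of 36 (camera adjusted p = 8.6e-05, adjusted p = 0.364 with an estimated correlation), were lower, with PSMA5 2.55-fold and PSMD8 3.23-fold lower. Histone genes fell in 13 of 16 cases with none higher (camera adjusted p = 1.6e-04, adjusted p = 0.423 with an estimated correlation), and H2BC12 fell 30.1-fold. The numbers of these 5 lists were the same adjusted over the list alone. The PI3K-AKT-mTOR activators, 20 up and 18 down of 51, and the negative regulators, 12 up and 13 down of 29, each the same adjusted over the list alone, did not pass (camera adjusted p = 0.818 and 0.999). Their medians of 0.11 and 0.15 turned to -0.10 and -0.22 on the TPM scale, which moved all genes by a median of -0.215 in this comparison. DEPTOR was at 49.96 ± 1.33 CPM in RPMI-8226 against 0.251 ± 0.0437 CPM, the kinase RPS6KA2 at least 275-fold higher, RPTOR 2.47-fold lower, TRIB3 6.79-fold lower and the insulin receptor adaptor GRB10 at least 441-fold lower. The hexokinase HK1 was 324-fold lower and the tumour suppressor CDKN2A at least 1692-fold higher in RPMI-8226.

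The test called 15401 of 20081 genes between RPMI-8226 and the libraries labelled NCI-BL2171, 8248 higher and 7153 lower, and 19 of 35 lists passed with the preset correlation and 0 with an estimated one. On the scale of log2(TPM + 1) limma-trend called 6472 higher and 7722 lower (45.6% higher, against 53.6%), so that the balance of directions depends on the scale.

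RPMI-8226-R was compared with the libraries labelled NCI-BL2171 in the same way. JCHAIN, MAF, IGFBP3, MZB1 and APP had the largest rises, each from no count, and were at least 16540-fold, 11310-fold, 8617-fold, 5440-fold and 4865-fold higher. The fetal and embryonic globins HBG1, HBG2 and HBE1, the tumour antigen PRAME and the glutathione transferase GSTP1 had the largest falls. HBG1, PRAME and GSTP1 were at least 53890-fold, 12780-fold and 11330-fold lower. PSMB5 was 1.86-fold lower in RPMI-8226-R, at 72.8 ± 8.86 against 135 ± 13 CPM (edgeR adjusted p = 1.0e-08). ABCG2 was 11.2-fold higher, at 114 ± 1.63 against 10.2 ± 1.26 CPM.

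Plasma cell identity genes rose in 22 and fell in 1 of 24 cases (camera adjusted p = 1.2e-08, adjusted p = 0.253 with an estimated correlation), with the prolyl isomerase FKBP11 36.4-fold higher. MHC class II genes rose in 12 of 13 cases (median 5.77, 2.97 with genes at 0 counts in a group at their bound, 0.83 on the TPM scale; camera adjusted p = 0.00306, adjusted p = 0.253 with an estimated correlation), and all 17 immunoproteasome and MHC class I genes rose (camera adjusted p = 1.2e-08, adjusted p = 0.244 with an estimated correlation). ATF4 targets fell in 26 and rose in 5 of 33 cases (camera adjusted p = 2.1e-05, adjusted p = 0.253 with an estimated correlation), with PPP1R15A 90.4-fold lower and the amino acid transporter SLC7A5 3.41-fold higher. Ribosomal protein mRNAs fell in 66 and rose in 3 of 75 cases (median -0.80, -0.62 on the TPM scale; camera adjusted p = 1.9e-10, adjusted p = 0.644 with an estimated correlation), and all 13 mitochondrially encoded mRNAs rose (median 2.06, 2.22 on the TPM scale; camera adjusted p = 4.0e-05, adjusted p = 0.610 with an estimated correlation). Each of these counts was the same adjusted over the list alone. The PI3K-AKT-mTOR activators, 24 up and 17 down, and the negative regulators, 11 up and 17 down, did not pass (camera adjusted p = 0.273 and 0.335). SGK1 was 37.2-fold and GAB2 20.5-fold lower, while DEPTOR was 14.1-fold higher, at 3.58 ± 0.283 against 0.251 ± 0.0437 CPM. The lysosomal protease CTSL had a count ratio (libraries labelled NCI-BL2171 over RPMI-8226-R) of 2086 (95% counting interval 714 to 10120).

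The test called 15540 of 20081 genes between RPMI-8226-R and the libraries labelled NCI-BL2171, 7872 higher and 7668 lower. On the scale of log2(TPM + 1) limma-trend called 7619 higher and 6472 lower. Of 35 lists 12 passed with the preset correlation and 0 with an estimated one.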

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

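The tests of a small erythroid share, of a swap, of antigen-presenting cells, of stressed cultures and of mitochondrial rRNA were chosen after the results were seen; the others below were written before theirs. The rules for outlying samples and for differences between groups under one contrast were not applied, because they need more libraries or groups than these.

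The libraries labelled NCI-BL2171 carried erythroid transcripts and lacked those of B cells. A small share of erythroid cells among B cells is argued against by the MHC class II genes. Of these, 0 of 13 reached 1 TPM. A swap with a library of RPMI-8226 or RPMI-8226-R is argued against by the lambda constant genes. They took at least 1.24% of the reads in each of the 4 other libraries. These shares cannot speak to a swap with a line outside this series. A line of the erythroid lineage under this label remains open: of 15 further erythroid genes, 12 had at least 5 TPM and at least 4-fold more than in both other lines, and MTAP, a 9p21 gene lost in the erythroleukaemia line K562, was at 0 TPM. HBG2, HBG1, HBE1 and GATA1 were chosen after their values were seen: HBG2 stood at 28530 ± 958, HBG1 at 13380 ± 289, HBE1 at 11970 ± 366 and GATA1 at 90.4 ± 5.31 TPM (mean ± SD). These values go with a line such as K562, but do not identify one, and no explanation beyond those above was tested.

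MHC class II, NF-kB and interferon genes were low in RPMI-8226-R. B or myeloid cells mixed into the RPMI-8226 libraries are argued against by a median of 0.196 TPM over 6 markers that such cells carry in abundance. For the MHC class II list, one outlying library is argued against by its highest camera adjusted p of 3.81e-08 over the 6 fits without 1 library. Cultures of RPMI-8226 under stress or crowded at harvest cannot be told apart from a difference between the lines. Each line has 1 culture state in this design. Immediate early genes had a median log2 fold change of -3.76. They were taken to rise in such a state, but whether stress or crowding raises them in these lines was not tested. The difference between the derivative and its parent that the design names stays open and untested.

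Ribosomal protein mRNAs fell and mitochondrial mRNAs rose in RPMI-8226-R, with medians of -0.77 and 1.33. Reads freed by less mitochondrial rRNA are too few to account for the rise, since they raise every other gene by 0.0189 on the log2 scale. This outcome was fixed by the shares, as that rRNA took at most 2.11% of the reads of a library. A rise of every gene also cannot give changes in opposite directions. Other differences in the removal of rRNA were not tested. A trend with transcript length accounts for part of the ribosomal protein fall, because removing it left a median of -0.411 (quartiles -0.546 and -0.289), only just past the bound of -0.4 set for the whole cause; it does not account for the mitochondrial rise, whose median was 1.56 after the same step. Removing a trend with GC content left the ribosomal protein median at -0.605 (quartiles -0.732 and -0.490). The scale of TPM moved the ribosomal protein median to -0.38 while moving all genes by 0.36; a difference between the lines stays open and untested.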

How the results depend on the processing

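The alternatives were planned before the data were examined. With a minimum of 2-fold, RPMI-8226-R against RPMI-8226 had 6683 genes (2362 higher, 4321 lower), RPMI-8226 against the libraries labelled NCI-BL2171 9780 (4156 lower) and RPMI-8226-R against those libraries 10119 (5180 higher, 4939 lower). The smaller numbers follow from the stricter threshold. With limma-trend on log2(TPM + 1), 4557 genes were lower in RPMI-8226-R than in RPMI-8226; the shift of that scale goes with it, but the cause was not tested. For gene lists, an estimated correlation left 0 calls in each comparison, where 18, 19 and 12 were made with the preset one. The estimated test rests on 3 residual degrees of freedom, so its 0 calls do not measure the effect of correlation alone. The fry test, which does not compare a list with other genes, called 30, 32 and 29. Of the lists that fry called, 3 had the other direction than with camera: heat shock genes in RPMI-8226-R against RPMI-8226 (adjusted p = 0.00918), myeloid markers in RPMI-8226 against the libraries labelled NCI-BL2171 (0.00181) and B cell identity in RPMI-8226-R against those libraries (0.00581); the cause was not tested. In windows of 100 genes along the chromosomes 2 passed, 0 of them higher, and in windows of 50 genes with an estimated correlation 0 passed.

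Leaving out 1 library at a time gave 11600 to 13192 genes for RPMI-8226-R against RPMI-8226 (5012 to 5697 higher, 6588 to 7504 lower, 17 to 19 lists), 14396 to 16281 for RPMI-8226 against the libraries labelled NCI-BL2171 (7778 to 8711 higher, 6529 to 7570 lower, 19 to 20 lists) and 14435 to 15683 for RPMI-8226-R against them (7398 to 7914 higher, 7037 to 7769 lower, 11 to 13 lists); a lone library was taken to vary like the others. Named genes lost their call in 27 gene-by-alternative cases where 1989 kept it (5 and 1099 with a library left out), and none changed direction. Depth limits genes with few counts, as for GRB10, ABCB1 and INPP5J.

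Replicate numbers did not pair the libraries: deviations from the line means of libraries with one number correlated at 0.0129, 0.0327 and -0.00351 across genes in the 3 comparisons, in the order above. With the number as a replicate block the test called 13045, 15295 and 15426 genes.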

Other observations

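The tests and genes of this part were chosen after the data were seen, except for the chromosome windows and the comparison with the level of the libraries labelled NCI-BL2171, which were planned. Ribosome biogenesis genes, which make and assemble rRNA, were higher in RPMI-8226-R than in RPMI-8226, with 39 of 40 higher and 0 lower (median log2 fold change 1.57; camera p = 9.3e-20, and p = 0.0170 with an estimated correlation, unadjusted). POLR1B, a subunit of RNA polymerase I, rose 5.60-fold to 102 ± 2.48 CPM, the snoRNP proteins NOP58 and DKC1 rose 2.84-fold and 2.50-fold, and nucleolin (NCL) rose 2.46-fold. Ribosomal protein mRNAs moved the other way in the same libraries.

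Immediate early genes were lower in RPMI-8226-R than in RPMI-8226 in 19 of 20 cases (median log2 fold change -3.76; camera p = 3.6e-10, and p = 0.105 with an estimated correlation, unadjusted). Against the libraries labelled NCI-BL2171, 18 of the 20 were higher and 2 lower in RPMI-8226 (median 2.50). In RPMI-8226-R against those libraries 6 were higher and 10 lower (median -0.63), so RPMI-8226 was the line with the high values. JUN fell from 803 ± 42.2 to 20.5 ± 0.655 CPM, FOS from 118 ± 14.3 to 3.34 ± 1.31 CPM and EGR1 from 43.9 ± 8.70 to 1.10 ± 0.504 CPM. Metallothioneins, which bind metals, fell in 6 of 6 cases (camera p = 0.00326, and p = 0.121 with an estimated correlation, unadjusted), MT2A 170-fold.

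FAF1 and CDKN2C, neighbours on chromosome 1 and singled out after their values were seen, had no count in RPMI-8226 or RPMI-8226-R and stood at 165 ± 2.39 and 67.1 ± 3.81 CPM in the libraries labelled NCI-BL2171. MTAP had no count in those libraries and 35.6 ± 1.73 CPM in RPMI-8226.

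Of 381 windows of 50 neighbouring genes, 4 (1.05%) differed from the rest of the genes in RPMI-8226-R against RPMI-8226 by camera, 2 of them higher; of windows of 100 genes 2 passed and 0 of them were higher. They lie on chromosome 6 at 31971091 to 33254989, where MHC class II genes are (adjusted p = 0.00116), chromosome 1 at 22117305 to 25859458, chromosome 12 at 123602077 to 132956304 and chromosome 16 at 67943474 to 70480274 (GRCh38). Gain or loss of segments cannot be told apart from shared regulation of neighbours at this share, and no window passed with an estimated correlation.

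Of the 13177 genes called between RPMI-8226-R and RPMI-8226, 61.5% moved toward the level of the libraries labelled NCI-BL2171. In 10 simulations of an unchanged line sharing the RPMI-8226 libraries, 53.1% of the 13177 genes with the lowest p did on average and 53.5% at most. Over all tested genes the difference was smaller, with 56.7% toward that level against 51.7% simulated. The simulated genes were ranked and not called. A line that differs from RPMI-8226 in unrelated ways was not simulated, so these shares are no baseline for called genes. Both other lines were higher than RPMI-8226 in 2560 genes, where independent lists would share 2036, and lower in 4229, where they would share 3065. These comparisons share the RPMI-8226 libraries, which independent lists leave out, so the excess is not a measure of a shared effect. The RPMI-8226 libraries were not divided between the comparisons, since each would keep 1.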
